A study of Mus musculus with 2 samples.

How the data were processed

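H3K4me3 was measured by ChIP-seq in hindbrain of mouse embryos of strain B6NCrl at embryonic day 10.5, in 2 biological replicates that pooled 69 and 51 embryos of both sexes. The deposited files were 4 peak lists in narrowPeak form on build mm10, 1 per replicate and 2 for the whole series. Per the deposited README texts, each replicate's list was derived from that replicate's own alignments and 2 further files that the texts do not describe. Per the same texts, the pooled list was derived from the alignments of both replicates, and the replicated list from both replicates' lists and the pooled list. Peaks were thus called per sample and also on pooled samples. Each peak of the replicated list was checked to be a peak of the pooled list with the same position and values. The aligner, the peak caller, its settings and thresholds were not given in the sources used here, nor was the control library, for which the labels name a possible experiment.

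Per peak, the position, the signal, the −log10 q value and the summit were read. The signal is the authors' own measure of each peak's strength as deposited, on a scale not stated in the sources used here. Signals were therefore compared within a list, or across genes of 1 list, and between replicates only by correlation of paired peaks. The −log10 q value is the authors' significance of the peak as deposited, and it was used only to set a stricter threshold. No file gave read counts, so the depth of each sample was unknown, no interval based on counts could be given, and a missing peak cannot be told from one below the threshold. The number of replicates, 2, limits the precision of each mean. With 1 group, no test between groups, no check of paired replicates and no regrouping of samples applied.

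Analyses were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3 for the exact Cochran-Mantel-Haenszel test. Peaks on chromosomes 1 to 19, X and Y were used. A peak counted as shared when its overlap with a peak of the other replicate covered at least 50% of either peak. The expectation by chance came from 100 circular shifts of the peaks within their chromosomes, with the random seed set to 1. Genes and TSSs came from the GENCODE vM21 annotation of the same build, with 21938 protein-coding genes and 132721 TSSs of all genes. A peak was assigned to a TSS when it overlapped the 1 kb on either side of one, else to an exon, an intron or intergenic sequence, in that order. Domains were peaks merged when at most 1 kb apart, and the width of a gene was that of its widest domain at a TSS. A gene was alone in its domain when no other protein-coding gene had a TSS within 1 kb of that domain. Non-coding genes were not counted for this. CpG content was the observed over expected ratio within 500 bp of the 5'-most TSS, from the mm10 sequence.

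Gene lists were tested against all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 22 lists and a threshold of 0.05. Of the 415 symbols in the 20 lists given by name, 411 were protein-coding genes in the annotation, and the others, H19, Kcnq1ot1, Meg3 and Airn, are non-coding RNA genes. The median width of each list's marked genes was ranked among 10000 random lists of the same size drawn from marked genes in the same signal deciles. These ranks describe the lists and carry no p-value. Pairs of lists were compared by two-sided permutation tests of the difference in medians with 100000 resamples. The lists, the tests of marking and breadth, the CpG comparison, the Hox regions and the alternatives in the closing section were fixed before the data were examined, except where the text says that a choice came later. Those later ones were the pairwise list tests, the ranking by signal, the comparison of chromosomes, the gene families and the added settings for breadth.

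Genes were named by a rule of 6 parts. It took a set of 10 Hox genes and 13 regulators fixed by name, and the 10 genes with the widest domain that was also at least 2 kb wide in each replicate. From each list it took the 3 marked genes with the widest domains and up to 3 unmarked genes in alphabetical order. It also took up to 6 list members per direction that were marked in 1 replicate's list alone, and the 5 strongest peaks with no TSS within 10 kb. Genes outside the rule are said to have been named after their values were seen.

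The procedures were tested on simulated data over the same 21938 genes. The overlap count differed from a brute-force count for 0 of 2093 peaks. Of 100 simulated lists of 20 genes marked at a rate of 98%, 90% were called higher, and of 100 marked at 30%, 85% were called lower. Of 200 random lists 3% were called. Of 100 lists of 20 genes whose domains were widened 1.5 times, 81% ranked in the top 2.5% by width, as did 1% of 200 random lists. Both were ranked in a pool that held the widened genes, so the 1% may understate the rate in the real data. Alternatives covered the overlap rule, the −log10 q threshold, equal list lengths, the sequences included, the TSS window, the choice of TSS, the list used, each replicate alone, shared promoters, the CpG background, the merging distance and the matching on signal.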

Results

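Trimethylation of histone H3 at lysine 4 (H3K4me3), a mark of active and poised promoters, was mapped by ChIP-seq in hindbrain of mouse embryos at embryonic day 10.5. The series held 1 group of 2 biological replicates, so no comparison between groups could be made. Replicate 1 pooled hindbrains of 69 embryos and replicate 2 those of 51, with both sexes in each pool. Peak lists were used for each replicate, for the pooled reads of both, and for the peaks of the pooled list that the authors counted as replicated. On chromosomes 1 to 19, X and Y, replicate 1 had 57338 peaks over 53.3 Mb and replicate 2 had 38158 over 46.2 Mb. The pooled list had 49839 over 56.1 Mb and the replicated list 31836 over 51.7 Mb. The lists gave no read counts, so the sequencing depth behind each value was unknown. Positions are 1-based on mouse build mm10.

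The first comparison asked which peaks were found in both pools of embryos. The strong peaks, most of them at transcription start sites (TSSs), were found in both. Each of the 15000 strongest peaks by signal in either replicate had a partner in the other's list. Of the 5000 strongest peaks, 99.7% in replicate 1 and 99.8% in replicate 2 lay at a TSS. Weak peaks were shared less: below rank 30000, 16.2% of replicate 1's peaks and 46.3% of replicate 2's had a partner. In all, 30396 of replicate 1's peaks (53.0%) and 31402 of replicate 2's (82.3%) were shared, where the overlap had to cover at least 50% of either peak. Peaks shifted at random within their chromosome were shared in 2.55% and 3.52% of cases on average, and in no more than 3.29% and 4.55% over 100 shifts. The shared stretches made up 79.9% of the length under replicate 1's peaks and 92.0% of that under replicate 2's. Across 32945 pairs of shared peaks, log10 signal had a Pearson correlation of 0.807 between replicates and signal a Spearman correlation of 0.778. Peaks are not independent, so no p-value was computed.

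The peaks of replicate 1 without a partner were short, weak and mostly away from TSSs. There were 26942 of them, with a median width of 201 bp and a median signal of 2.87, against 1177 bp and 12.7 for its shared peaks. Of the unshared peaks, 23.0% lay at a TSS and 41.8% in introns, and of the shared ones 59.6% and 16.2%. Replicate 2 had 6756 unshared peaks, with a median width of 223 bp and 19.9% at a TSS. The replicated list kept 63.9% of the pooled list's peaks and 92.1% of its length. The kept peaks had a median width of 1203 bp and 57.6% lay at a TSS, whereas the 18003 others had a median of 219 bp and 22.5% at a TSS.

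The next comparison asked where in the genome the mark lay. Of the 31836 replicated peaks, 18336 (57.6%) overlapped the 1 kb on either side of an annotated TSS, and they held 79.8% of the peak length. Randomly shifted peaks lay there in 10.4% of cases (SD 0.449 over 100 shifts, highest 11.7%). Peaks at TSSs had a median width of 2056 bp and a median signal of 37.4, against 669 bp and 4.82 for intergenic peaks. Introns held 17.3% of the peaks, against 31.6% of the shifted ones. Intergenic sequence held 17.7%, against 49.1%. The share at TSSs was 42.4% in replicate 1's list and 51.7% in replicate 2's.

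Most protein-coding genes carried the mark, and a smaller share of each other gene class that was counted did. A gene was counted as marked when a peak overlapped the 1 kb on either side of any of its TSSs. In the replicated list 14879 of 21938 protein-coding genes (67.8%) were marked, against 15175 (69.2%) in replicate 1 and 14874 (67.8%) in replicate 2. Both replicates marked 14823 genes, replicate 1 alone 352 and replicate 2 alone 51. The first count is below the 14879 of the replicated list, so a gene marked there need not be marked in both own lists. Of 5854 genes for long intergenic non-coding RNAs, 1081 (18.5%) were marked, 675 of them by a peak that touched no protein-coding TSS. Antisense RNA genes were marked in 39.1% of 2959 cases, microRNA genes in 18.1% of 2202 and processed pseudogenes in 2.68% of 9940.

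Marked and unmarked genes differed in promoter sequence. CpG dinucleotides, which are clustered in CpG islands at many promoters, had a median observed over expected ratio of 0.702 within 500 bp of the TSS of marked genes and 0.164 for unmarked ones. The share of marked genes was 6.43% in the lowest decile of promoters by this ratio, 50.4% in the fourth, 85.0% in the fifth and 99.6% in the highest. Because of this relation, each gene list described next was also tested within deciles of promoter CpG content, by the exact Cochran-Mantel-Haenszel test. That background was chosen in advance, and its adjusted p is printed where it changed a call. A list marked in full can lose its call there with no fall in its share, since no higher share is possible.

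The Hox clusters, whose genes are used in order along the body axis, were compared because the hindbrain uses the genes of the first 4 paralog groups. Peaks lay thickly over those genes in 3 of the 4 clusters. Within gene bodies of paralogs 1 to 4, replicated peaks covered 94.2% of the length in the Hoxb cluster, 47.2% in Hoxd, 42.2% in Hoxa and 11.3% in Hoxc. The Hoxc value rests on 1 gene, Hoxc4. The values for paralogs 5 to 13 were 16.6%, 20.8%, 15.4% and 7.48%. In both replicates the order between the 2 parts was the same in each cluster. One domain of 37.7 kb ran over Hoxb2, Hoxb3 and Hoxb4 (chromosome 11, 96317805 to 96355529). It measured 38.8 kb in replicate 1, and in replicate 2 it broke into a piece of 23.9 kb at Hoxb2 and Hoxb3 and 1 of 4.28 kb at Hoxb4. Another domain of 24.3 kb covered Hoxa1 and Hoxa2 (chromosome 6, 52156645 to 52180926), with 24.8 and 24.3 kb in replicates 1 and 2. Its peak signal was 48.9.

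Single Hox genes outside those domains had narrower peaks. Hoxb1 had a domain of 2.00 kb with a signal of 10.6, and Hoxd4 one of 3.60 kb with 14.0. At the opposite ends of the clusters, which act in the tail and limb buds, Hoxa13 had 1.49 kb with a signal of 11.2, Hoxd13 1.10 kb with 13.3, Hoxc13 1.01 kb with 5.59 and Hoxb13 0.309 kb with 3.98. The widest domains among paralogs 5 to 13 were 1.79 kb at Hoxb8, 1.65 kb at Hoxb6 and 1.65 kb at Hoxa5. Hoxa9, Hoxc11 and Hoxc12 were among the unmarked genes. Hoxa9, Hoxa10, Hoxc8 and Hoxc9 were marked in replicate 1's own list and not in replicate 2's, and Hoxa11 the reverse.

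In all, 33 of the 39 Hox genes were marked. All 12 genes of paralogs 1 to 4 were (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 0.0170 over 22 lists), and 21 of the 27 of paralogs 5 to 13 (adjusted p = 0.344 by the same exact test). Within deciles of promoter CpG content the first call was lost (adjusted p = 0.0912 by the exact Cochran-Mantel-Haenszel test). Paralogs 5 to 13 were then marked less often than comparable promoters, with 77.8% against 95.01% (adjusted p = 0.00238 by that exact test). With only the TSS at the 5' end of each gene, 10 of the 12 were marked (adjusted p = 0.270, Fisher's exact test). Marked paralogs 1 to 4 had a median domain width of 6.59 kb and paralogs 5 to 13 of 1.07 kb (permutation test, adjusted p = 0.0003 over 6 tests chosen after the values were seen). Their median peak signals were 16.3 and 5.27 (permutation test, adjusted p = 0.00072). Genes that share a domain are not independent in these tests, and the width difference was smaller in replicate 2's own list, with 3.74 against 0.756 kb. The median of paralogs 1 to 4 was 3.58 kb without merging of peaks. It was 2.01 kb for the 6 genes with no other protein-coding gene in their domain.

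By cluster, replicated peaks covered 32.1% of Hoxa (chromosome 6, 52155590 to 52260880), 29.8% of Hoxd (chromosome 2, 74668310 to 74765142), 25.8% of Hoxb (chromosome 11, 96194316 to 96368256) and 6.79% of Hoxc (chromosome 15, 102921103 to 103036852). The replicates' own lists gave 31.0% ± 2.02 (SD, n = 2), 28.8% ± 3.39, 23.8% ± 2.27 and 6.64% ± 2.29 in the same order. Covered lengths were 44.9 kb of 174 in Hoxb, 33.8 of 105 in Hoxa, 28.8 of 96.8 in Hoxd and 7.86 of 116 in Hoxc. The Hoxb interval includes a stretch without a replicated peak, from 96194558 at Hoxb13 to the next peak at 96271373. Of the Hoxc genes 5 of 9 were marked, against 10 of 11 in Hoxa, 10 of 10 in Hoxb and 8 of 9 in Hoxd.

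**Figure D1:**
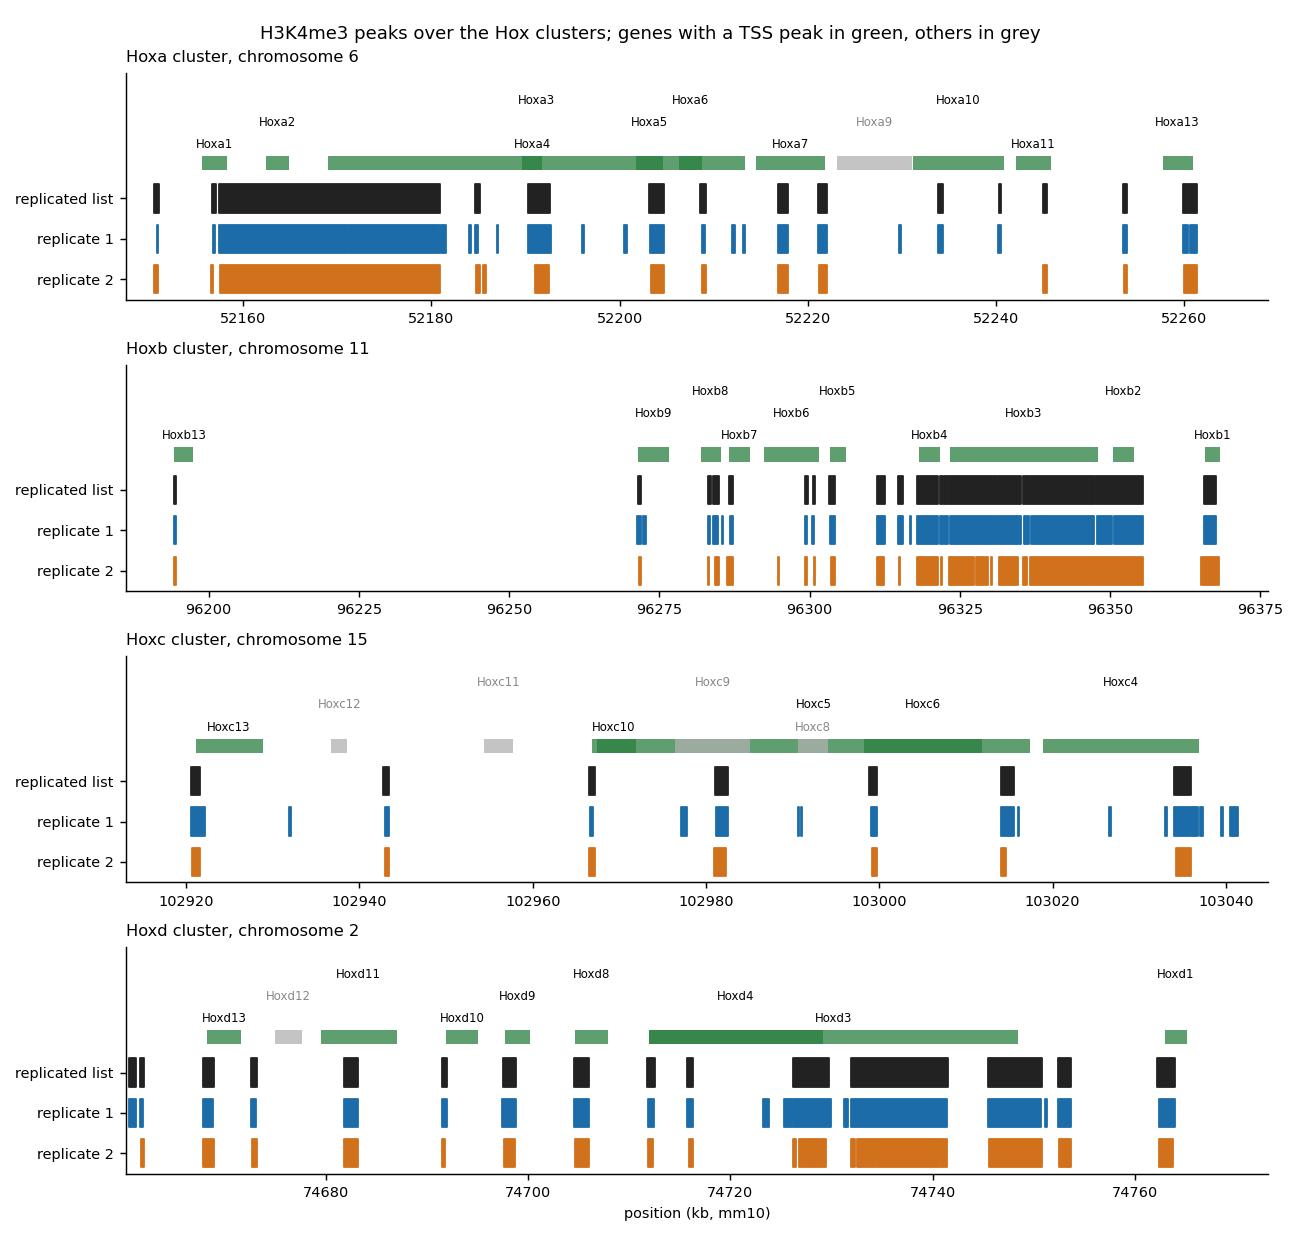
H3K4me3 peaks over the 4 Hox clusters, plotted against position in kb on mm10, with the replicated list in black, replicate 1 in blue and replicate 2 in orange; Hox genes are green where a replicated peak lies at the TSS and grey otherwise. Peaks cover 32.1% of Hoxa, 25.8% of Hoxb, 6.79% of Hoxc and 29.8% of Hoxd.

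The genes that pattern the hindbrain along its length and from dorsal to ventral were all marked, mostly by domains several kilobases wide. The list for rhombomeres and the isthmus, the organizing centre at the border with the midbrain, had 30 of 30 genes marked in the replicated list and in each replicate (Fisher's exact test, adjusted p = 5.79e-05). Egr2, which specifies odd-numbered rhombomeres, had a domain of 6.18 kb (chromosome 10, 67534975 to 67541156), with 6.15 and 6.17 kb in replicates 1 and 2. Mafb, a regulator of posterior rhombomeres, had 6.10 kb (6.87 and 5.83 kb). Gbx2, which sets the anterior limit of the hindbrain, had 10.5 kb (14.5 and 9.94 kb). The engrailed genes of the isthmus region had 15.9 kb at En1 (15.4 and 15.8 kb) and 19.1 kb at En2 (18.8 and 19.3 kb). The widest domains of the list were 21.2 kb at Meis2, a Hox cofactor, 19.2 kb at Pax5 and that of En2.

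The dorsoventral and rhombic lip list had 33 of 33 genes marked (Fisher's exact test, adjusted p = 2.63e-05). Its widest domain lay at Pax6, a regulator of ventral and rhombic lip progenitors, with 25.1 kb in the replicated list and 17.3 and 24.9 kb in replicates 1 and 2. Zic1 and Zic4 shared a domain of 21.3 kb (21.4 and 13.6 kb). Atoh1, which specifies rhombic lip neurons, had 5.17 kb and a signal of 28.2. Phox2b, which specifies visceral motor neurons, had 7.79 kb and a lower signal of 9.57. Within deciles of promoter CpG content the call of this list was lost, since 94.4% of comparable promoters were marked (adjusted p = 0.221, exact Cochran-Mantel-Haenszel test).

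Regulators of other brain regions were marked as well. All 24 genes of the forebrain and midbrain list were (Fisher's exact test, adjusted p = 0.000302). Otx2, a determinant of forebrain and midbrain, had a domain of 13.8 kb (chromosome 14, 48661119 to 48674882), with 14.9 and 8.66 kb in replicates 1 and 2 and a signal of 16.6. Foxg1, a regulator of the telencephalon, had 6.64 kb (6.55 and 3.62 kb) and a signal of 16.8. Otx1 had 16.3 kb and Lhx2 12.9 kb. Beside the 63 genes of both hindbrain patterning lists, these genes had a lower median signal, 17.5 against 29.2 (permutation test, adjusted p = 0.0162). They also had a lower median width, 4.53 against 7.82 kb (permutation test, adjusted p = 0.0258). These 2 tests were chosen after the values were seen. The marking call was lost within deciles of promoter CpG content (adjusted p = 0.0563, exact Cochran-Mantel-Haenszel test).

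Genes of dividing neural progenitors and of new neurons were both marked, the former with the higher signal. Of the progenitor genes 21 of 21 were marked (Fisher's exact test, adjusted p = 0.00116). Sox2, which keeps neural progenitors undifferentiated, had a domain of 21.4 kb (21.0 and 21.4 kb in replicates 1 and 2). Notch1 had 20.7 kb (23.5 and 6.19 kb), Msi1 14.7 kb with a signal of 70.5, and Nes, the gene of the progenitor filament nestin, 5.63 kb with a signal of 54.0. Of the neuronal genes 34 of 35 were marked (Fisher's exact test, adjusted p = 0.00012), and Tph2, the gene for serotonin synthesis, was not. The neuronal tubulin gene Tubb3 had 8.29 kb (8.27 and 7.45 kb). The widest neuronal domains lay at transcription factor genes, 16.8 kb at Lhx5, 14.9 kb at Gata3 and 11.6 kb at Gata2. That at Gata3 also covered 4930412O13Rik and 9230102O04Rik, and measured 15.4 and 10.5 kb in replicates 1 and 2. Median signal was 48.3 for progenitor and 25.1 for neuronal genes (permutation test, adjusted p = 0.0003), and median width 7.38 against 4.86 kb (permutation test, adjusted p = 0.0955). Both tests were chosen after the values were seen. Within deciles of promoter CpG content the call of the progenitor list was lost (adjusted p = 0.0526, exact Cochran-Mantel-Haenszel test).

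Among other cell types of the head, neural crest and vessel genes were marked more often than other genes. Of the neural crest and mesenchyme genes 21 of 22 were marked (Fisher's exact test, adjusted p = 0.00725), with domains of 14.1 kb at Tfap2a, 9.04 kb at Pdgfra and 9.0 kb at Tfap2b, and none at Lum. All 14 endothelial genes were marked (Fisher's exact test, adjusted p = 0.0108), with 6.84 kb at Fli1, 4.64 kb at Esam and 4.40 kb at Kdr, the gene of a receptor for vascular growth factor. The endothelial call depended on weak peaks. In replicate 2's own list 12 of the 14 genes were marked (Fisher's exact test, adjusted p = 0.290), and Tek and Tie1, named after their values were seen, were not. At −log10 q of at least 5, 10 of the 14 were marked (adjusted p = 1, Fisher's exact test), and with a peak at the TSS itself 11 (adjusted p = 0.408, Fisher's exact test).

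Of the glial genes 8 of 12 were marked (Fisher's exact test, adjusted p = 1), and 7 and 6 in the own lists of replicates 1 and 2. Only 5 of the 12 were marked at −log10 q of at least 5, with the TSS itself, or with only the 5'-most TSS. None of these settings gave a call. Slc1a2, the gene of an astrocyte glutamate transporter, had 5.89 kb with a signal of 49.9, Cnp had 2.66 kb and Mbp 2.42 kb. The myelin genes Mag, Mobp and Mog were unmarked. Aqp4 and Gfap were marked in replicate 1's own list alone and Plp1 in replicate 2's alone. Of the blood and myeloid genes 5 of 18 were marked, fewer than among other genes (Fisher's exact test, adjusted p = 0.00116). The marked ones included the blood regulators Tal1 with 8.49 kb and Runx1 with 5.64 kb, and the erythropoietin receptor gene Epor with 4.25 kb. Csf1r and Cx3cr1, expressed in microglia, were unmarked, and Aif1, Hba-x and Hbb-bh1 were marked in replicate 1's own list alone. The blood call was lost in the pooled list, with 9 of 18 marked (adjusted p = 0.158, Fisher's exact test), and within deciles of promoter CpG content (adjusted p = 1, exact Cochran-Mantel-Haenszel test).

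Genes of liver, pancreas and gut and of epidermis and lymphocytes were marked less often than other genes. Of the liver, pancreas and gut genes 6 of 18 were marked (Fisher's exact test, adjusted p = 0.00629). The marked ones included Lgr5 with 3.78 kb, Foxa3, whose domain of 3.57 kb also covered Sympk, and Sox17 with 2.33 kb, which the endothelial list holds too. Alb, Afp and Apob, genes of proteins secreted by the liver, were unmarked. Apoa1 and Vil1 were marked in replicate 2's own list alone. Of the epidermis and lymphocyte genes 3 of 16 were marked (Fisher's exact test, adjusted p = 0.00024), namely Lor, Krt10 and Krt1 with 2.38, 2.14 and 1.13 kb. The lymphocyte genes Cd19, Cd3e and Cd3g were unmarked. When each gene was given its 5'-most TSS alone, 1 of the 16 was marked. Within deciles of promoter CpG content both calls were lost (adjusted p = 0.0912 and 0.330, exact Cochran-Mantel-Haenszel test).

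Of the muscle and heart genes 7 of 16 were marked (Fisher's exact test, adjusted p = 0.0700), with 2.49 kb at Myod1, 1.77 kb at Hand2 and 1.55 kb at Des. Acta1, Actc1 and Myf5 were unmarked, and Tbx5 was marked in replicate 2's own list alone. With a peak required at the TSS itself, 4 of the 16 were marked and the list passed the threshold (adjusted p = 0.00181, Fisher's exact test). Of the germline genes 4 of 14 were marked (Fisher's exact test, adjusted p = 0.0055). They included Dazl with 1.14 kb, Ddx4 with 0.447 kb and Gdf9, whose domain of 2.58 kb also covered Uqcrq, whereas Acrv1, Mael and Prm1 were unmarked. Of the pluripotency genes 8 of 12 were marked (Fisher's exact test, adjusted p = 1). The widest domains there were 7.27 kb at Tbx3, 4.78 kb at Klf4 and 1.98 kb at Esrrb, and Dppa5a, Nanog and Pou5f1 were unmarked.

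Genes of the cell cycle and of the ribosome were all marked in these lists. The cell cycle list had 20 of 20 genes (Fisher's exact test, adjusted p = 0.00116), with 7.84 kb at Pcna, 6.70 kb at Rrm2 and 5.08 kb at Mcm7. The ribosomal protein list had 46 of 46 (Fisher's exact test, adjusted p = 1.81e-07), with 11.1 kb at Rps15, 10.3 kb at Rpl19 and 9.61 kb at Rpl13a, each in a domain shared with a neighbouring gene. Both lists have CpG-rich promoters, and within deciles of CpG content the calls were lost (adjusted p = 1 and 0.0526, exact Cochran-Mantel-Haenszel test).

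Of the imprinted protein-coding genes 16 of 17 were marked (Fisher's exact test, adjusted p = 0.0236), with 10.3 kb at Gnas, 9.13 kb at Mkrn3 and 9.12 kb at Nnat, and none at Ndn. That call was lost with the 5'-most TSS of each gene, at 13 of 17 (adjusted p = 0.469, Fisher's exact test), and without genes that share a promoter, at 11 of 12 (adjusted p = 0.0818, Fisher's exact test), where the list was smaller but its share, 91.7% against 63.6% of other genes, was not closer to theirs. All 4 Y-linked genes were marked (adjusted p = 0.344, Fisher's exact test), with 2.02 kb at Eif2s3y, 2.00 kb at Ddx3y and 1.81 kb at Uty. Even marked in full, a list of 4 genes was too small to be called. Of 1135 olfactory receptor genes 4 were marked, and of 329 vomeronasal receptor genes 1, Vmn1r4, in a promoter shared with another gene (Fisher's exact test, adjusted p = 3.87e-161). For the olfactory receptors the p was too small to be represented.

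Counted over the 22 lists, 11 were marked more often than other genes, 6 less often and 5 were not called (Fisher's exact test, Benjamini-Hochberg adjustment). Replicate 1's own list gave 11, 6 and 5, and replicate 2's 10, 6 and 6. Within deciles of promoter CpG content 5 lists were marked more often, those of rhombomere and isthmus patterning, neurons, neural crest and mesenchyme, endothelium and imprinted genes. That CpG content was taken at the 5'-most TSS, whereas a peak at any TSS counted, so peaks at other TSSs may add to an excess. Of the imprinted genes 16 of 17 were marked at any TSS but 13 at the 5'-most one. The other lists among these were still called higher by Fisher's exact test with the 5'-most TSS alone. Lists that lost their higher call there were marked in full, against 82.1% (Hox paralogs 1 to 4) to 98.3% (cell cycle) of comparable promoters. No higher share was possible, so these lost calls do not show that an excess was absent. Genes of a list are not independent replicates.

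**Figure D2:**
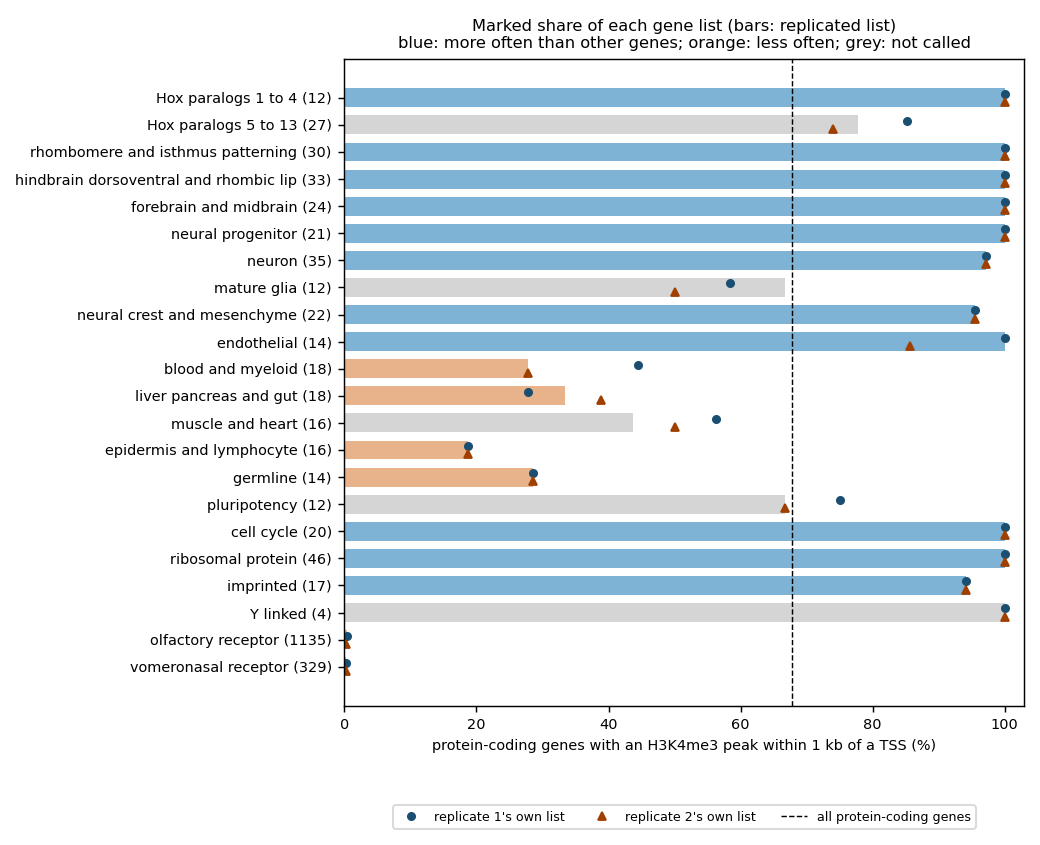
Percent of each list's genes with a peak at the TSS, with bars for the replicated list (blue higher than other genes, orange lower, grey not called), circles for replicate 1, triangles for replicate 2 and a dashed line at 67.8%, the share of all protein-coding genes. The 30 rhombomere and isthmus genes stand at 100%, and the epidermis and lymphocyte genes at 18.8%.

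Several lists of developmental regulators, and the imprinted list, had wider domains than other marked genes of like signal. Marked protein-coding genes had a median domain of 2.62 kb, 10% of them exceeded 5.19 kb and 210 reached 10 kb. Each list's median was ranked among 10000 random lists of marked genes drawn from the same deciles of signal. The dorsoventral list had 8.31 kb (random lists 1.90), neural progenitors 7.38 (2.78), Hox paralogs 1 to 4 6.59 (1.65), rhombomere and isthmus genes 6.16 (2.33) and imprinted genes 6.04 (2.30). Neuronal genes had 4.86 kb (1.97), neural crest and mesenchyme genes 4.81 (1.78) and forebrain and midbrain genes 4.53 (1.59). These 8 lists lay at the 100th percentile, and in each replicate at the 99.99th or above, but Hox paralogs 1 to 4 fell to 94.6 among the 6 genes alone in their domain, a setting added after the data were seen. Cell cycle, ribosomal protein and blood genes, at 3.96, 3.77 and 4.25 kb, also ranked in the top 2.5%, but not under every setting. Cell cycle genes fell to percentile 94.3 at −log10 q of at least 5, with 96.8 when peaks up to 3 kb apart were merged and 97.1 in replicate 2's own list. Ribosomal protein genes fell to 94.5 among the 31 genes alone in their domain, and to 97.4 with the wider merging. Blood genes fell to 90.4 in replicate 1's own list, where their median was 2.41 kb, to 96.2 in replicate 2's, to 97.1 without merging and to 95.9 when not matched on signal. Olfactory receptors, at 0.401 kb, and mature glia, at 0.829 kb, ranked in the bottom 2.5%, but in neither replicate's own list. There olfactory receptors lay at percentiles 3.11 and 3.67 and mature glia at 9.55 and 35.1 in replicates 1 and 2. Paralogs 5 to 13, at 1.07 kb, lay at the 46.9th percentile and at 11.3 in replicate 2's own list. They lay at 0 when random lists were not matched on signal or were matched on signal and CpG number, the latter added after the data were seen. That added setting matched signal in quintiles and not deciles, so the fall cannot be credited to CpG number alone. Without merging of peaks the medians fell to 5.51 kb for the dorsoventral, 3.03 for the neural crest and mesenchyme and 2.88 for the forebrain and midbrain list, still at the 100th percentile.

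By peak signal the order was another one. Against random lists of marked genes, whose median was 45.4, ribosomal protein genes (57.9) and cell cycle genes (54.8) ranked in the top 2.5% of the lists. A total of 15 lists ranked in the bottom 2.5%, among them paralogs 5 to 13 (5.27), endothelial genes (9.26), Hox paralogs 1 to 4 (16.3), forebrain and midbrain genes (17.5), neuronal genes (25.1) and dorsoventral genes (27.1). Progenitor genes (48.3) lay at the 77.0th percentile and rhombomere and isthmus genes (37.97) at the 3.03rd. The latter list ranked at 9.29 in replicate 1's own list and in the bottom 2.5% in replicate 2's, at 0.52. Mature glia left the bottom 2.5% in replicate 2's list, at 3.22, and blood genes entered it in replicate 1's, at 0.22. This ranking by signal was added after the data were seen.

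**Figure D3:**
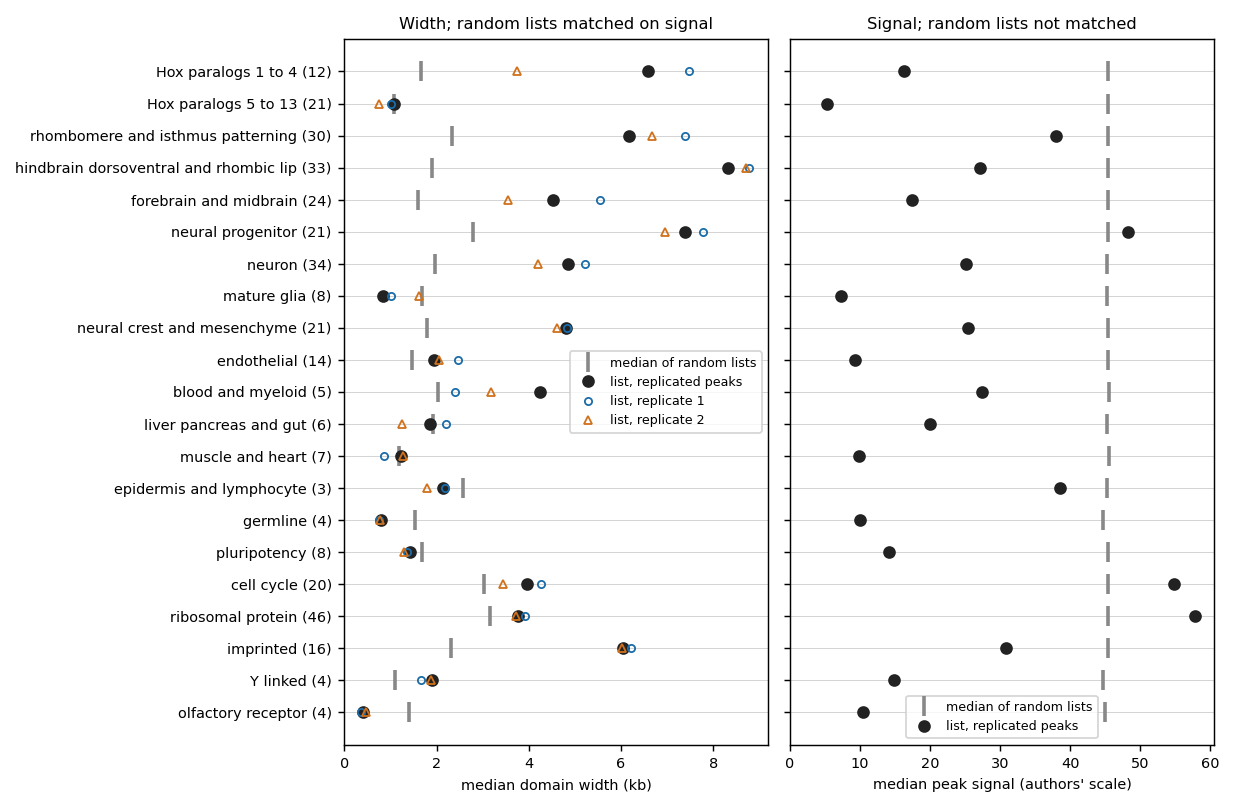
Median width in kb of the TSS domain of each gene list (left) and its median peak signal (right), with black points for the replicated list, open circles for replicate 1, open triangles for replicate 2 and grey ticks for the median of 10000 random lists of marked genes, matched on signal in the left panel. The dorsoventral list stands at 8.31 kb against 1.90 kb for its random lists, with a signal of 27.1 against 45.4.

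The widest domain, 41.6 kb on chromosome 10 (80134923 to 80176526), ran over 1600002K03Rik, Atp5d, Cbarp, Cirbp and Midn. It measured 52.7 kb in replicate 1, and in replicate 2 it gave 28.7 kb for 4 of the genes and 4.40 kb for 1600002K03Rik. Next came the domain of Hoxb2, Hoxb3 and Hoxb4, then Pou3f3 with 31.6 kb (chromosome 1, 42683355 to 42714969) and Nr2f1 with 31.0 kb (chromosome 13, 78174840 to 78205805). Pou3f3, a neural transcription factor gene, measured 31.6 and 30.9 kb in replicates 1 and 2, and Nr2f1, which encodes a nuclear receptor, 37.9 and 30.8 kb. Further wide domains, named after their values were seen, were 1 over A930004D18Rik, Mllt10 and Skida1 (chromosome 2, 18036879 to 18066878), 29.2 kb at Nr2f2, 23.6 kb at Zfhx3 (12.7 and 9.78 kb in replicates 1 and 2), 23.2 kb at Pou3f2, 22.96 kb at Bahcc1, 22.2 kb at Ptch1, the receptor gene of hedgehog signalling, 19.1 kb at Pax7 and 17.7 kb at Pax3.

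Peaks far from any annotated TSS were mostly weak and narrow. Of the replicated peaks 5593 (17.6%) had no TSS within 10 kb, with a median width of 644 bp and a median signal of 4.36. The 5 strongest had signals of TSS peaks. They lay at chromosome 9, 67631607 to 67634789 (signal 52.2, intergenic, nearest protein-coding TSS that of Tln2 at 73.5 kb), and chromosome 9, 32031367 to 32034415 (52.1, intergenic, Arhgap32 at 83.2 kb). The others were at chromosome 4, 46304023 to 46305878 (51.9, in an intron of Gm12446, Foxe1 at 38.7 kb), chromosome 14, 76151264 to 76153862 (50.5, intergenic, Nufip1 at 41.7 kb), and chromosome 11, 8622772 to 8625571 (49.1, in an intron of Tns3). All 5 had a peak in each replicate, with signals of 39.5 to 42.2 in replicate 1 and 49.4 to 54.4 in replicate 2.

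Chromosome X stood apart from the autosomes in this comparison, which was chosen after the values were seen. Of its 948 protein-coding genes 494 (52.1%) were marked, against 56.7% to 81.6% on the 19 autosomes. The median TSS peak signal of the marked genes was 28.2, against 43.4 to 48.2 on the autosomes. The replicates' own lists gave 23.9 and 27.7 for chromosome X, below their lowest autosomes at 35.5 and 44.1. Chromosome Y had 7 replicated peaks and 4 marked genes of 183.

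**Figure D4:**
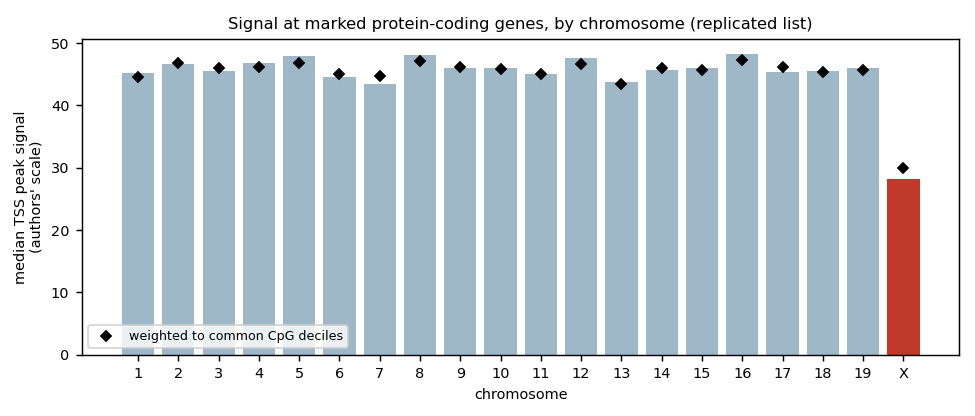
Median TSS peak signal of marked protein-coding genes on each chromosome (bars, X in red) in the replicated list, with diamonds for medians weighted to the same promoter CpG content. Chromosome X stands at 28.2 and the lowest autosome at 43.4, or at 29.99 and 43.5 after weighting.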

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

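The tests on replicate 1's unshared peaks were chosen after the result was seen. Peaks on sequences outside chromosomes 1 to 19, X and Y were used in no comparison, and with no control samples any count above 3 was listed for a closer look. The replicated list held 15 such peaks on 6 sequences, with a median signal of 6.82 and a highest signal of 46.5. The replicates' own lists held 24 and 13.

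Replicate 1's own list had 26942 peaks without a partner and replicate 2's had 6756, a difference of 20186. Fragments of domains that both replicates share were 1 candidate explanation. Of replicate 1's unshared peaks 40.7% lay within 1 kb of one of its shared peaks, against 41.5% in replicate 2, so most of the excess was not of that kind. Calls close to the threshold were the other: counting only unshared peaks with −log10 q of at least 5 left 1386 and 176, which is 5.99% of the difference. That decides nothing, since unshared peaks were weak in both lists (5.14% and 2.61% reached that value) and the ratio of replicate 1 to replicate 2 was 3.99 before and 7.88 after. Whether depth, the control library or the threshold gave the excess stays open, and no biological explanation was tested.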

How the results depend on the processing

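The alternatives were planned, except the matching on CpG number, the genes alone in their domain and the ranking by signal, which were added after the data were seen. The number of marked protein-coding genes, 14879, ranged from 14092 to 15175 over the other settings. Lists marked less often numbered 4 to 7 (6 as reported), and lists in the top 2.5% by width 9 to 11 (11). Marked Hox genes (33) numbered 31 to 35 leaving out a replicate or at −log10 q of at least 5. Of paralogs 5 to 13, 14 of 27 were marked with the TSS itself and 18 with only the 5'-most TSS, against 21. Of the values that lead each comparison, 57 stayed within their limits under an alternative and 32 did not. The latter follow, and the cause was not tested unless stated.

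Shared peaks were 56.7% of replicate 1's and 86.4% of replicate 2's with any overlap of 1 bp, 45.0% and 67.6% with 50% of both peaks, 86.0% and 95.8% at −log10 q of at least 5 in both lists, and 73.1% and 77.0% with lists of equal length. The correlation of log10 signal was 0.755, 0.983 and 0.908 with any overlap, 50% of both peaks and −log10 q of at least 5. At that threshold 97.8% of the pooled peaks were kept as replicated. The share of peaks at a TSS was 50.5% for the TSS itself and 66.3% within 2.5 kb, which follows from the window. It was 44.9% in the pooled list, 47.3% with only the 5'-most TSS, and 42.4% to 51.7% leaving out a replicate. With CpG counted within 1 kb of the TSS, 4.15% of the lowest and 99.68% of the highest decile were marked, and the medians differed by 0.438. With the median over all TSSs these were 2.69%, 99.5% and 0.430. Leaving out a replicate gave 29.6% to 32.4% of the Hoxa cluster covered and 22.2% to 25.4% of Hoxb.

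Within the same CpG deciles 5 lists, not 11, were marked more often. The lists that lost this call were marked in full, so their share could go no higher. In the bottom 2.5% by width there were 2 lists as reported, 1 with peaks merged within 3 kb, 6 not matched on signal, 1 at −log10 q of at least 5, 4 matched on signal and CpG number, and 0 to 1 leaving out a replicate, the 1 being germline genes and not a list reported as narrow. Values that turned were those of lists with no call as reported, and the width of mature glia. Hox paralogs 5 to 13 differed from other genes by −14.5 percentage points with the TSS itself, which did not pass (adjusted p = 0.176, Fisher's exact test), and by −17.2 within the same CpG deciles, which did (adjusted p = 0.00238, exact Cochran-Mantel-Haenszel test). Pluripotency genes differed by −1.13 to 5.83 points leaving out a replicate, 14.3 in the pooled list and 3.10 without genes sharing a promoter. Mature glia differed by 3.10 points without such genes and 20.6 within the same CpG deciles, and its width stood at percentile 75.6 with peaks merged within 3 kb and 51.2 at −log10 q of at least 5. Among single lists, 16 more values lost a call and 1 gained it, 61 width percentiles moved by more than the spread between replicates, and 279 values did neither. No paired analysis was possible because the series has 1 group.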

Other observations

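The gene families, the comparison of chromosomes and the tests of wide domains by genes alone in their domain and of X copy number were chosen after the values were seen. Unlike the lists, none of the 28 families was tested within deciles of promoter CpG content, so their calls may follow that content. All 19 Sox genes were marked (Fisher's exact test, adjusted p = 0.00163 over 28 families), with a median domain of 6.88 kb. All 19 Wnt genes (adjusted p = 0.00163) and 39 of 44 Fox genes were marked as well (adjusted p = 0.0032, Fisher's exact test). Tbx genes, with 11 of 14 marked, and Fgf genes, with 17 of 22, were not called (adjusted p = 0.590 and 0.532, Fisher's exact test). The Zic, Irx and Lhx families were marked in full but were too small to be called (unadjusted p = 0.183, 0.186 and 0.0611, Fisher's exact test). Pax genes, with 8 of 9 marked, were not called either (adjusted p = 0.322, Fisher's exact test). These families had wide domains: the median was 14.7 kb for 5 Zic genes, 12.4 kb for 8 marked Pax genes, 9.82 kb for 6 Irx genes and 8.81 kb for 8 Lhx genes. Axon guidance families were marked almost throughout, with 32 of 33 semaphorin, plexin and netrin genes (adjusted p = 0.000242) and 22 of 22 ephrin and Eph receptor genes (adjusted p = 0.000662, Fisher's exact test). Glutamate receptor genes were marked in 24 of 24 cases (adjusted p = 0.000257) and GABA-A receptor genes in 14 of 19 (adjusted p = 0.806, Fisher's exact test).

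Of the clustered protocadherins, adhesion genes of neurons, some groups were marked more and others less often than other genes. Of the gamma genes 20 of 21 were marked (Fisher's exact test, adjusted p = 0.00681), against 2 of 14 alpha genes (adjusted p = 0.000154, Fisher's exact test) and 1 of 22 beta genes (adjusted p = 2.38e-09, Fisher's exact test). Most marks of the gamma genes were weak and narrow, with a median signal of 8.10 and a median width of 1.03 kb. All marked protein-coding genes had medians of 45.4 and 2.62 kb. The marked alpha genes were Pcdhac1 and Pcdhac2, and the beta gene was Pcdhb1. Zinc finger genes named Zfp were marked in 323 of 365 cases (Fisher's exact test, adjusted p = 2.37e-19), with a median width of 2.27 kb, below each of the random lists of like signal. Keratin genes (9 of 49), cytochrome P450 genes (27 of 93) and beta-defensin genes (0 of 42) were marked less often than other genes (adjusted p = 6.12e-12, 1.52e-13 and 2.67e-20, Fisher's exact test). Among non-coding genes named after their values were seen, Malat1 had a domain of 9.81 kb with a signal of 55.1, Kcnq1ot1 4.57 kb with 35.7 and Xist 3.90 kb with 15.8. Hotairm1 lay in the domain of Hoxa1, and Hottip and Hotair were unmarked.

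Of the developmental lists, 7 had wider domains than genes of like signal: Hox paralogs 1 to 4, rhombomere and isthmus, dorsoventral, forebrain and midbrain, progenitor, neuron, and neural crest and mesenchyme genes. Hox paralogs 5 to 13 did not, at percentile 46.9, and imprinted genes, at 100, were wide too. More CpG dinucleotides around their TSSs may account for part of this. Random lists matched on signal and on the number of CpGs within 5 kb had a median of 3.33 kb, against 1.90 kb, for the dorsoventral list (8.31 kb observed). For the forebrain and midbrain list they had 2.87 kb, against 1.59 kb (4.53 kb observed). That matching set signal in quintiles and not deciles, so the rise cannot be credited to CpG number alone. With no matching on signal the random medians were 2.61 and 2.63 kb. With signal and CpG number matched, the lowest percentile of the 7 lists was still 99.4, which argues against CpG number, as matched here, as the whole cause. The matching was by quintiles, around the 5'-most TSS, so CpG differences within a quintile or beyond 5 kb were not set aside. Domains that run over several protein-coding genes might account for part of the width too. However, among genes alone in their domain the 6 lists without Hox genes all stayed at the 100th percentile. Hox paralogs 1 to 4 fell to 94.6, so for them the question stays open. Domains that run over non-coding genes were not set aside: Sox2 counted as alone but shared its domain with Sox2ot. Differences between cell types in a mixed tissue could not be tested with 1 group, and no biological explanation was tested.

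Marked X-linked genes had a median signal of 28.2, below each autosome. Promoter CpG content was 1 candidate explanation, but weighting genes to the same CpG deciles gave 29.99 for chromosome X against 43.5 to 47.3 for the autosomes. A lower number of X copies in pools with male embryos may contribute. The ratio of the X median to the median over the 19 autosomes was 0.614, which lies between the values that male pools and equal copies would give, but the share of male embryos is not known and the signal need not scale with copies, so this stays open. Inactivation of 1 X in female cells was not tested.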
